A study of Mus musculus with 90 samples.

How the data were processed

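RNA from 90 mouse melanoma allograft tumours was measured on 3 prime expression arrays with 45101 probe sets. Per the labels, each tumour was subcutaneous, carried the genotype label Hgftg;Cdk4R24C/R24C and came from strain B6.cBrd, and 800 ng of RNA was amplified and labelled with biotin. The deposited values are on the log2 scale and lie between 2.19 and 14.84, with array medians between 5.71 and 5.90. The authors name RMA, which summarises and normalizes probe sets, and limma, with no version; whether both studies were normalized together is not given in the sources used here. An array gives no counts, so the number of arrays limits the precision.

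Tumours were grouped by study and outcome label into 12 groups. The animal numbers in the labels differ for every tumour, so p-values measure the spread between tumours. In study 3 the PBS, IgG and anti-PD-L1 tumours carry separate blocks of animal numbers, so in that study a control comparison and a possible difference between cohorts cannot be told apart. This does not hold for comparisons among anti-PD-L1 tumours.

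Probe sets that name 1 gene symbol were kept (34958), and those with several symbols (932) or none (9211) were left out. Of each gene's probe sets the one with the highest mean over all arrays stood for the gene, which gave 18194 genes, 9012 of them with over 1 probe set. All 90 arrays were fitted together with limma 3.58.1 in R 4.3.3, with 1 mean per group. Comparisons were contrasts of these means, averaged with equal weights over both studies where both hold the groups. Tests were 2-sided and adjusted by Benjamini-Hochberg over all genes, with a threshold of 0.05. Errors of log2 fold changes are limma's standard errors (SE).

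Before the data were examined, 30 gene lists were written from general knowledge of cell types and pathways. They hold 429 entries, of which 388 were measured. The 29 lists with at least 5 measured members were tested with limma's camera at its preset correlation of 0.01, adjusted over the lists of each comparison, with an estimated correlation and with fry. The mean log2 value of 7 lists was also taken per tumour and compared between responders and non-responders by a 2-sided permutation test within study (100000 resamples).

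The rule for the genes that the text names was fixed at the same time. In the 3 comparisons among responder, non-responder and IgG tumours it takes the 10 largest rises and 10 largest falls past the threshold with the same sign in both studies, and 3 members of each list by p. In other comparisons it takes the 5 largest rises and falls past the threshold. A fixed set was added (Cd274, Pdcd1, Hgf, Cdk4, Cd8a, Gzmb, Ifng, Foxp3, Mlana and Mki67, and 1 gene that is not reported here). Some members of the set are left out for length.

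Alternatives fixed at the same time were a trend in the prior variance, array weights, the mean of all probe sets, a filter on dim genes, median centring, quantile normalization within study, the 3 prime to 5 prime difference of the Actb and Gapdh control probe sets as a covariate, ignoring study, pooling PBS with IgG, counting stabilization as response, fitting only the groups compared, a threshold of 0.01, scores from standardized values, and leaving out each tumour of groups with 2 to 5. Chosen after seeing the data were leaving out 5 tumours low in melanocyte transcripts, leaving out study 2 non-responder replicate 14, a second method of array weights, the skeletal muscle list as a covariate, and the 3 prime to 5 prime covariate with 1 array far from the rest left out. For each comparison with at least 3 tumours per group, 100 splits of the tumours were counted, the real one included.

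The procedure was tested on simulated data with the group sizes of the study. With changes in 50 genes for each size, the responder against non-responder comparison recovered 98% of genes changed by 0.5 on the log2 scale, with 15 false calls. Stabilization against responder recovered 42% at that size and growth delay against IgG 30%. The simulated genes varied independently of each other, each with the same spread in every group. Real genes move together and groups differ in spread, so these rates may not hold for the real data. Splits of the real tumours, described above, gave up to 367 genes for responder against non-responder.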

Results

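The arrays profiled whole melanoma tumours from mice given an antibody against PD-L1, the ligand that restrains T cells through PD-1, or a control. Study 2 held 17 responder, 14 non-responder, 3 relapse, 2 growth delay, 14 IgG and 3 PBS tumours. Study 3 held 10 responder, 9 non-responder, 3 relapse, 3 stabilization, 8 IgG and 4 PBS tumours. Responders shrank by at least 5% under anti-PD-L1, and non-responders kept growing and were taken at comparable times. Relapse tumours had shrunk below a measurable size and grew back during dosing. Stabilization tumours are responders whose volume did not move between 2 measurements, and growth delay tumours appeared only after treatment. The sample labels give 10 mg/kg for both antibodies and 10 ml/kg for PBS, while the description of the series also names 20 mg/kg for the antibodies.

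In 5 of the 90 tumours the melanocyte differentiation list had a mean below 9 on the log2 scale. Study 2 non-responder replicate 14 had a mean of 8.22, with B cell and T cell means of 9.80 and 8.98. Study 3 responder replicate 3 had a mean of 6.97, with a B cell mean of 10.14, a T cell mean of 9.13 and an adipocyte mean of 10.10. Study 3 responder replicate 4 had 7.01 and a skeletal muscle mean of 13.12. In study 3 stabilization replicate 1 the mean was 7.11, beside a fibroblast mean of 12.65, and in replicate 2 it was 8.60, beside a skeletal muscle mean of 11.20. Counts that move by over 1.5 times without these tumours are given with both values.

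**Figure D1:**
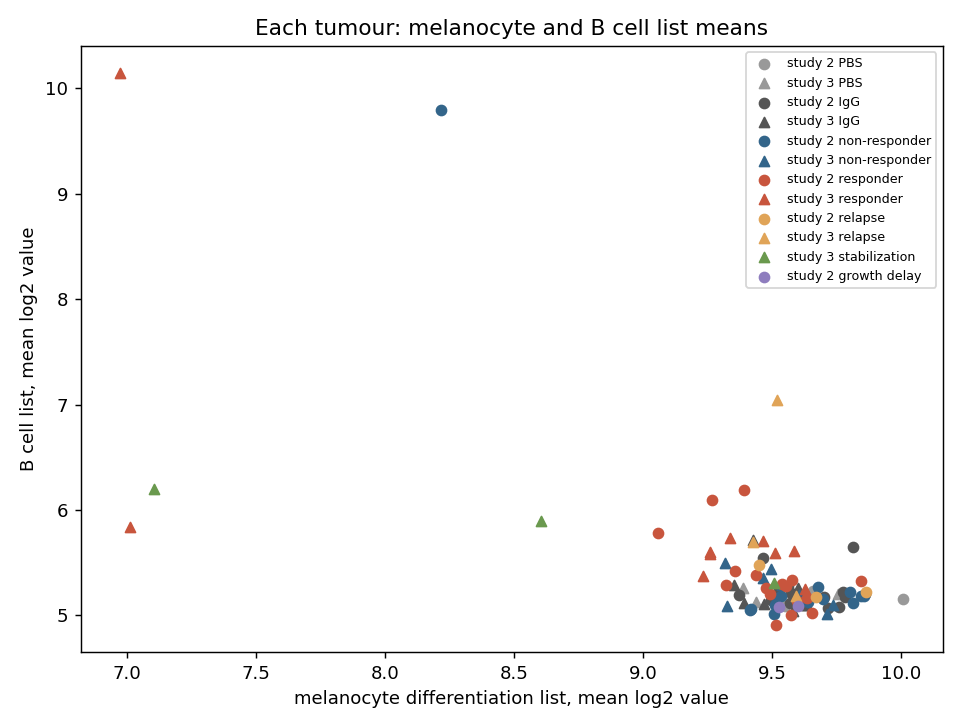
Each point is 1 of the 90 tumours, with the mean log2 array value of the melanocyte differentiation list on the x axis and that of the B cell list on the y axis, coloured by outcome and shaped by study. Study 2 non-responder replicate 14 (9.80) and study 3 responder replicate 3 (10.14) have the highest B cell means.

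The first comparison asked how tumours that regressed under anti-PD-L1 differed from tumours that grew under it. Regressing tumours carried more T cell, cytotoxic and interferon gamma transcripts. Cd3g, a chain of the T cell receptor complex, was higher by 2.14 ± 0.34 on the log2 scale (SE; 17 and 10 responders against 14 and 9 non-responders), 4.40-fold. Ubd, an interferon-inducible ubiquitin-like modifier, had the largest rise, 2.32 ± 0.41, and the guanylate-binding proteins Gbp2b and Gbp8 rose by 2.08 ± 0.34 and 2.02 ± 0.32. Ifng itself rose by 1.61 ± 0.26, 3.06-fold, with an adjusted p of 2.36e-05. Cd274, which encodes PD-L1, the target of the antibody, rose by 0.80 ± 0.12, and Pdcd1, which encodes its receptor PD-1, rose by 1.30 ± 0.22.

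Of 16 measured cytotoxic effector genes 14 rose, none fell and 2 did not pass, and 16 rose when adjusted over the list alone. Examples are Ccl5, a chemokine of T cells (1.71 ± 0.27), Tbx21, the T-bet transcription factor (1.67 ± 0.26), and Gzmb, a granule protease (1.49 ± 0.32). Cd8a, the CD8 co-receptor, which is also in the cytotoxic list, rose by 1.30 ± 0.23. In the T cell list 12 of 14 rose and 1 fell, with 12 rises and 1 fall adjusted over the list alone. Of 13 checkpoint and exhaustion genes 11 rose and 0 fell, the same numbers adjusted over the list alone. They include Pdcd1lg2, the second ligand of PD-1 (0.96 ± 0.17). Of 15 interferon gamma response genes 14 rose and 1 fell, also adjusted over the list alone, among them Cxcl9, a chemokine that draws T cells (1.53 ± 0.28), and Socs1, an inhibitor of cytokine signalling (0.75 ± 0.14). These 4 lists were shifted upward by camera (adjusted p 2.17e-12, 6.71e-08, 1.44e-08 and 1.85e-09). None of them passed with an estimated correlation, where the adjusted p was 0.188 for the cytotoxic, checkpoint and interferon gamma lists and 0.211 for the T cell list.

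Antigen presentation genes rose as well. All 11 measured MHC class I genes passed upward, also adjusted over the list alone, with Tap2, a peptide transporter, at 0.92 ± 0.16. In the MHC class II list 9 of 10 rose and 0 fell, and 10 adjusted over the list alone, with H2-Ab1 at 1.59 ± 0.27 and H2-DMa, which helps load peptides, at 1.52 ± 0.24. Both lists had an adjusted p of 0.188 with an estimated correlation. Averaged over both studies, the type I interferon list had 5 rises, 2 falls and 11 genes that did not pass (4 and 2 adjusted over the list alone), with a camera adjusted p of 0.137 and 0.686 with an estimated correlation. That camera value was 0.000968 without the 5 tumours low in melanocyte transcripts. The list passed upward by camera within study 2 (adjusted p = 0.000684) and against IgG (adjusted p = 0.00489). Within study 3 it did not pass by camera (adjusted p = 0.869), but did without those tumours (adjusted p = 0.00524).

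Myeloid and stromal transcripts were also higher. In the macrophage list 15 of 16 genes rose and 0 fell, the same adjusted over the list alone, including Csf1r, the receptor for the macrophage growth factor CSF1 (1.40 ± 0.28), Mertk, a receptor for dying cells (0.79 ± 0.16), and C1qc, a complement component (0.97 ± 0.19). The dendritic cell list had 5 rises among 13 genes, 5 adjusted over the list alone, with Irf8, a transcription factor of these cells, at 1.49 ± 0.24. By camera that list passed within study 3 (adjusted p = 0.000328) and not within study 2 (adjusted p = 0.0991). Fibroblast and extracellular matrix genes rose in 15 of 16 cases, also adjusted over the list alone. Examples are Pdgfra (1.21 ± 0.32, with 1 of its 3 probe sets passing), Pdgfrb (0.90 ± 0.24) and the collagen gene Col5a1 (0.97 ± 0.24). Endothelial genes had 7 rises among 14, also adjusted over the list alone, with Pecam1 at 0.65 ± 0.21. With an estimated correlation the adjusted p was 0.211 for macrophage, 0.302 for dendritic cell and fibroblast, and 0.392 for endothelium.

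Among antibody-producing cell genes, 6 of 11 plasma cell and immunoglobulin genes rose and 0 fell, and 7 rose adjusted over the list alone. Jchain, the joining chain of secreted antibodies, rose by 1.99 ± 0.46 and Prdm1, a plasma cell regulator, by 1.11 ± 0.22. The B cell list had 4 rises among 14 and 1 adjusted over the list alone, with Blnk, a signalling adaptor, at 1.07 ± 0.29. The adjusted p with an estimated correlation was 0.339 for the plasma cell list and 0.602 for the B cell list, and 1 of the tumours with a B cell mean above 9 lies on each side of the comparison. Of 9 adipocyte genes 5 rose, also adjusted over the list alone, with Lipe, a lipase of fat cells, at 0.79 ± 0.21 (1 of its 2 probe sets passed), and the adjusted p was 0.392 with an estimated correlation. Adipocyte means were 5.92 in responders against 6.05 in non-responders of study 2, and 7.33 against 5.92 in study 3. The plasma cell, B cell and adipocyte lists passed upward by camera within study 3 only. Within study 2 their camera adjusted p was 0.106, 0.487 and 0.836, with the B cell and adipocyte lists downward. None of the 14 skeletal muscle genes passed, over all genes or adjusted over the list alone.

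In the pigment cell and proliferation lists 0 genes rose. Their falls came at about the rate of all genes, where 5885 of 18194 fell. In the melanocyte differentiation list 0 rose, 6 fell and 11 did not pass, with 5 falls adjusted over the list alone. Pmel, a melanosome structural protein, changed by -1.03 ± 0.31, Gpr143, a melanosome receptor, by -0.77 ± 0.21, and Mlana by -0.67 ± 0.30, which did not pass (adjusted p = 0.0536). Of 22 cell cycle genes 7 fell and 0 rose, with 6 falls adjusted over the list alone, among them Bub1, a mitotic checkpoint kinase (-0.46 ± 0.14). Mki67 had a value of 0.25 ± 0.13 and did not pass. Neither list passed by camera (adjusted p 0.130 and 0.506, and 0.602 and 0.882 with an estimated correlation). Without the 5 tumours low in melanocyte transcripts the camera adjusted p was 0.608 and 0.752, with the cell cycle list upward. The per-tumour list means differed by -0.05 and 0.02 in study 2, and by -0.60 and -0.24 in study 3. Among the largest falls were those of Gsta4, a glutathione transferase (-1.43 ± 0.28), Slc26a7, an anion transporter (-1.30 ± 0.28), Gng8, a G protein subunit (-1.11 ± 0.22), and Ptgds, a prostaglandin synthase (-0.999 ± 0.237). Of the engineered genes of the model, Cdk4 fell by 0.38 ± 0.10 and Hgf had a value of -0.42 ± 0.27 that did not pass. For Hgf the value was 0.24 in study 2, which did not pass, and -1.08 ± 0.42 in study 3 (adjusted p = 0.0369), and of its 3 probe sets, which ran from -0.42 to 0.19, 1 passed upward. Foxp3, the regulatory T cell factor, had a value of -0.04 ± 0.06 and did not pass either.

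Other lists shifted upward were inflammatory chemokines and receptors (11 rose, 2 fell of 16), neutrophil (6 rose of 12), NK cell (4 rose of 7), alternatively activated macrophage (5 rose of 13), hypoxia and glycolysis (6 rose, 1 fell of 16), immediate early and heat shock (4 rose, 1 fell of 12) and dedifferentiated melanoma (3 rose of 12). Adjusted over the list alone, the rises numbered 12, 6, 4, 5, 3, 4 and 1, in that order, and the falls 2, 0, 0, 0, 0, 1 and 0. None of them passed with an estimated correlation (adjusted p 0.211, 0.302, 0.339, 0.378, 0.427, 0.409 and 0.378). Within study 2 the neutrophil, NK cell and alternatively activated macrophage lists did not pass by camera (adjusted p 0.0742, 0.461 and 0.110). Within study 3 the hypoxia, immediate early and dedifferentiated melanoma lists did not (camera adjusted p 0.157, 0.0541 and 0.1005). The immediate early list also did not pass by camera without the 5 tumours low in melanocyte transcripts (adjusted p = 0.0698). Not shifted were lymphoid chemokines (3 rose, 1 fell of 9), regulatory T cell (3 rose, 1 fell of 8), mast cell and eosinophil (4 rose of 11), keratinocyte (5 fell of 13) and Wnt target genes (2 rose, 4 fell of 12). Their counts were the same adjusted over the list alone. The lymphoid chemokine list passed upward by camera without those 5 tumours (adjusted p 0.0352 in place of 0.0521). With an estimated correlation their adjusted p was 0.427, 0.427, 0.556, 0.638 and 0.882. For mast cell and eosinophil genes the median was below 0 with the mean and test upward, for Wnt targets the mean was above 0 with the median and test downward, and for skeletal muscle the median and mean were below 0 with the test upward.

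Over all 18194 genes, 3434 were higher and 5885 lower in responders. Changes of at least 2-fold were found in 263 higher and 5 lower genes. Of the 9012 genes with over 1 probe set, 540 had probe sets that passed in opposite directions. Among the 7278 genes in the 4 dimmest deciles 484 were higher and 3080 lower, and in the rest 2950 were higher and 2805 lower. Within that rest the brightest decile had 323 higher and 655 lower. The per-tumour mean of the cytotoxic list was 7.57 ± 0.87 (SD, n = 17) in study 2 responders and 6.79 ± 0.98 (n = 14) in non-responders. In study 3 it was 8.44 ± 0.56 (n = 10) against 6.84 ± 0.53 (n = 9), with IgG tumours at 6.62 ± 0.53 (n = 14) and 6.65 ± 0.62 (n = 8). Averaged over studies the responder mean was higher by 1.20 (permutation p = 1e-05, the smallest the resamples can give; adjusted p = 7e-05 over 7 lists). The differences for the interferon gamma, macrophage and fibroblast lists were 0.74, 0.82 and 0.90 (permutation test, adjusted p 7e-05, 0.00014 and 0.000788). Those for the B cell, melanocyte and cell cycle lists were 0.35, -0.32 and -0.11 and did not pass (permutation test, adjusted p 0.409, 0.116 and 0.409). The B cell difference was -0.11 in study 2 and 0.81 in study 3. Without study 2 non-responder replicate 14 the B cell and melanocyte differences passed, at 0.51 and -0.38 (permutation test, adjusted p 0.000252 and 0.00576). They also passed without all 5 tumours low in melanocyte transcripts, where they were smaller, at 0.27 and -0.13 (permutation test, adjusted p 0.000308 and 0.00908).

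**Figure D2:**
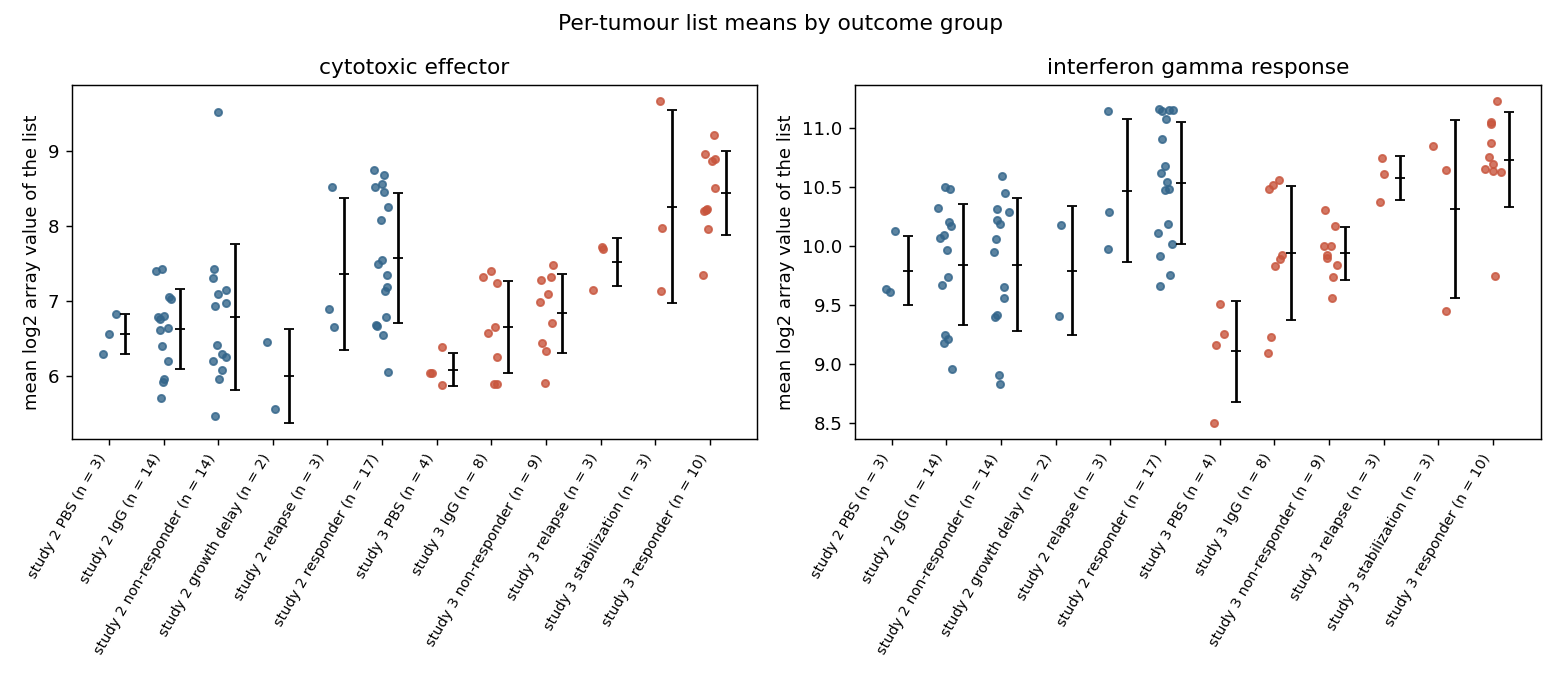
Each point is a tumour, with the mean log2 array value of the cytotoxic effector list (left) and the interferon gamma response list (right) on the y axis and the 12 groups on the x axis. Bars give the group mean and SD, and the cytotoxic mean was 8.44 in study 3 responders and 6.84 in study 3 non-responders, with groups that overlap in both studies and both panels.

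Within study 2 alone, interferon gamma response genes had 10 rises among 15 genes and 13 adjusted over the list alone (adjusted p = 0.321 with an estimated correlation). Ubd rose by 1.87 ± 0.51, Cd3g by 1.54 ± 0.42 and Ifng by 1.21 ± 0.32, while Cd8a (0.83 ± 0.28) and Gzmb (1.06 ± 0.39) did not pass. Within study 3 the same genes had larger values, with Ubd at 2.77 ± 0.65, Cd3g at 2.73 ± 0.54, Ifng at 2.02 ± 0.41, Cd8a at 1.77 ± 0.36 and Gzmb at 1.92 ± 0.50. Study 3 also had a rise in Adipoq, the fat cell hormone adiponectin, of 3.26 ± 0.92. The studies gave 478 genes (112 higher, 366 lower) and 6680 genes (2611 higher, 4069 lower). Of the 478 genes, 449 (93.9%) had the same sign in study 3, against 79.7% over all genes. Of the 478, 209 also passed there with the same sign, where 36.7% of all genes passed. Across genes, which are not independent replicates, the log2 fold changes had a Pearson correlation of 0.731. The difference between the studies passed for 0 genes by limma, with 2418 at an unadjusted p under 0.05. Without the 5 tumours low in melanocyte transcripts the counts were 4529 and 2275, and 2872 for study 2 without non-responder replicate 14 alone. With only the compared groups fitted they were 169 and 3141.

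**Figure D3:**
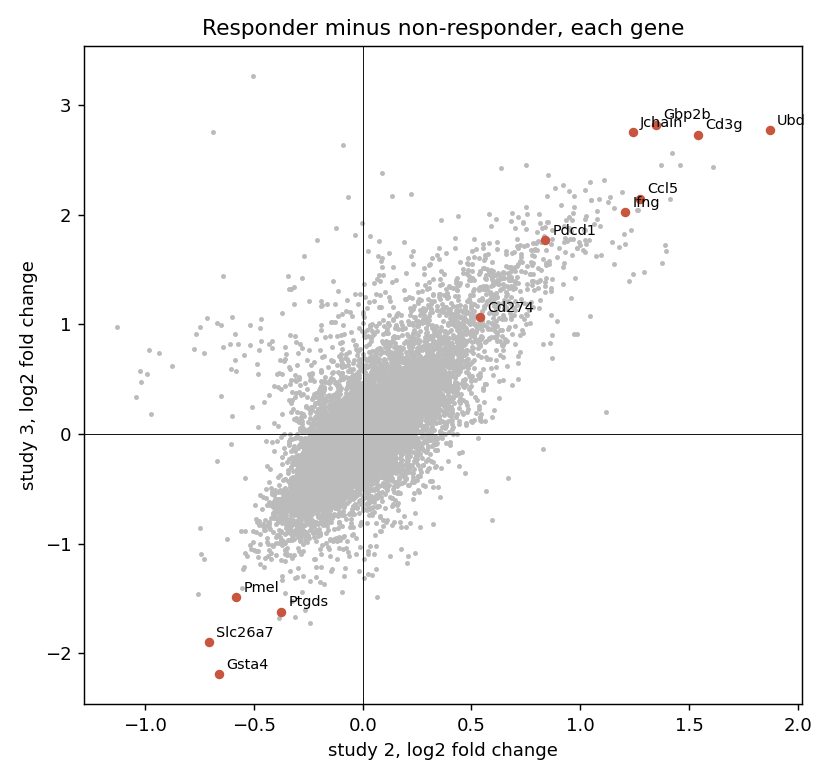
Each point is a gene, with its log2 fold change of responder against non-responder tumours in study 2 on the x axis and in study 3 on the y axis, and 12 genes named. Ubd lies at 1.87 and 2.77, and Gsta4 at -0.66 and -2.19.

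Against the IgG control, regressing tumours showed higher T cell and interferon gamma transcripts too. Cd3g rose by 2.34 ± 0.35, 5.07-fold, and Gbp2b by 2.39 ± 0.35, 5.24-fold (SE; 17 and 10 responders against 14 and 8 IgG tumours). Nkg7, a cytotoxic granule protein, rose by 1.89 ± 0.29, Cxcr6, a homing receptor of tissue T cells, by 1.99 ± 0.33, and Ifng by 1.77 ± 0.27. Inhibitory receptors rose as well, with Pdcd1 at 1.48 ± 0.22, Havcr2, which encodes TIM-3, at 1.35 ± 0.21 and Ctla4 at 0.88 ± 0.14. Cd274 rose by 0.73 ± 0.13. Among falls, Gsta4 changed by -1.51 ± 0.28, Slc26a7 by -1.37 ± 0.28 and Pmel by -1.17 ± 0.32.

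Of 16 cytotoxic genes 15 rose, of 15 interferon gamma genes 14 rose and 1 fell, of 14 T cell genes 12 rose and of 13 checkpoint genes 11 rose, each count the same adjusted over the list alone. All 11 MHC class I and all 10 class II genes rose, also adjusted over the list alone. For these 6 lists the adjusted p was 0.106 with an estimated correlation. Of 16 macrophage genes 12 rose (15 adjusted over the list alone), with C1qc at 0.91 ± 0.19, and of 16 fibroblast genes 5 rose (10 adjusted over the list alone), with Col5a1 at 0.78 ± 0.24. Their adjusted p was 0.271 and 0.425 with an estimated correlation. The fibroblast list passed by camera within study 3 (adjusted p = 1.28e-05; means 10.54 against 9.45) and not within study 2 (adjusted p = 0.223; 9.67 against 9.56). The melanocyte list was the 1 list shifted downward, with 5 of 17 falling and 2 adjusted over the list alone. It did not pass with an estimated correlation (adjusted p = 0.467), nor by camera without the 5 tumours low in melanocyte transcripts (adjusted p = 0.386). Mlana, a melanocyte antigen, changed by -0.77 ± 0.31 and by -0.33 without those tumours, where it did not pass (adjusted p = 0.210). In all, 20 lists were shifted upward by camera and none passed with an estimated correlation. Without the 5 tumours the adipocyte, endothelium and neutrophil lists did not pass by camera either (adjusted p 0.184, 0.161 and 0.0692). The hypoxia and glycolysis list passed upward by camera there (adjusted p 0.0373 in place of 0.195). By limma 2784 genes were higher and 3652 lower, and without the 5 tumours 1886 and 2013. Within study 2 the counts were 1980 higher and 2993 lower, and within study 3 1674 and 1488. The study 3 total of 3162 was 1070 without the 5 tumours, 1102 with only the compared groups fitted, and 908 with the 3 prime to 5 prime covariate and the array of the largest difference left out. Responder and IgG tumours also differ in their block of animal numbers in both studies.

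Tumours that grew under anti-PD-L1 were compared with IgG tumours to ask whether treatment without regression left a mark on expression. The T cell and target genes had small values that did not pass, with Cd8a at 0.23 ± 0.24, Gzmb at 0.28 ± 0.34, Ifng at 0.16 ± 0.28, Pdcd1 at 0.18 ± 0.23 and Cd274 at -0.07 ± 0.13 (SE; 14 and 9 non-responders against 14 and 8 IgG tumours). The neutrophil genes S100a8 and S100a9 had values of -0.84 ± 0.41 and -0.83 ± 0.39 and did not pass. Dleu7 was the 1 gene that passed (0.33 ± 0.06, adjusted p = 0.00415). It is dim, and its group means were 3.53 in IgG and 3.57 in non-responders of study 2, and 3.58 and 4.20 in study 3. By limma 1101 genes had an unadjusted p under 0.05. Dleu7 did not pass with study ignored (adjusted p = 0.9999) or with PBS pooled into the control (adjusted p = 0.535).

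Camera shifted 6 lists in this comparison, and 0 of their members passed over all genes or adjusted over the list alone. Those lists were fibroblast, hypoxia, macrophage, alternatively activated macrophage and neutrophil, all downward, and type I interferon, upward, with medians of -0.30, -0.13, -0.11, -0.14, -0.07 and 0.08. Each had an adjusted p of 0.960 with an estimated correlation. The 5 downward lists passed by camera within study 2 and none of them within study 3, where the adjusted p was at least 0.586. Type I interferon passed in neither study alone. Within study 2 limma called 0 genes, with 749 at an unadjusted p under 0.05. Within study 3 it called 126, of which 122 were higher, among them Mapk15, an atypical MAP kinase (0.51 ± 0.10), and 4 lower, among them Ccnj, a cyclin (-0.70 ± 0.16). That count was 1 with only the compared groups fitted, 36 with the filter on dim genes and 31 with the 3 prime to 5 prime covariate and the array of the largest difference left out. It was 275 without the 5 tumours low in melanocyte transcripts, 256 with the mean of all probe sets and 443 with default array weights. In both studies the groups also differ in their block of animal numbers.

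Relapse tumours were compared with responders and with non-responders, to place regrowth under treatment between those outcomes. The description of the series gives 2 to 12 doses before harvest and 4 to 10 doses before regrowth. These comparisons may therefore mix outcome with length of treatment. The cytotoxic list mean of relapse tumours was 7.35 ± 1.02 in study 2 and 7.52 ± 0.32 in study 3 (SD, n = 3 in each). In study 3 this lay between the responder and non-responder means, and in study 2 it rested on replicate 1 (8.52), with 6.89 and 6.65 in the others. Against responders, Gzmb had a value of -1.07 ± 0.49, Ifng of -0.90 ± 0.41, Cd8a of -0.67 ± 0.35, Cd274 of -0.39 ± 0.19 and Mlana of 0.67 ± 0.47, none of which passed. By limma 0 genes passed, with 962 at an unadjusted p under 0.05. Camera shifted the T cell, cytotoxic, checkpoint, inflammatory chemokine, neutrophil and hypoxia lists downward and the cell cycle, melanocyte and type I interferon lists upward. In these 9 lists 0 members passed over all genes or adjusted over the list alone, and the adjusted p with an estimated correlation was 0.909 for hypoxia and 0.542 for the other 8. Without the 5 tumours low in melanocyte transcripts the cell cycle list did not pass by camera (adjusted p = 0.111), and the fibroblast, B cell and adipocyte lists were shifted upward (adjusted p 0.00292, 0.00348 and 0.0314) and the NK cell list downward (adjusted p = 0.0314).

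Against non-responders, relapse tumours had higher transcripts of single antibody and matrix genes. Jchain was higher by 2.09 ± 0.73, Col1a1, the main fibrillar collagen gene, by 1.93 ± 0.62 and Itih5, a hyaluronan-binding matrix protein, by 1.98 ± 0.58 (SE; 3 and 3 against 14 and 9). Gsta4 and Ptgds were lower (-1.31 ± 0.44 and -1.12 ± 0.38), while Cd8a (0.63 ± 0.36), Gzmb (0.42 ± 0.50) and Cd274 (0.41 ± 0.20) did not pass. Fibroblast genes rose in 8 of 16 cases (15 adjusted over the list alone), interferon gamma genes in 8 of 15 (11) and MHC class II genes in 6 of 10 (7), while plasma cell and immunoglobulin genes rose in 2 of 11 (2) and did not pass by camera (adjusted p = 0.0611, and 0.704 with an estimated correlation). That list passed upward by camera without the 5 tumours low in melanocyte transcripts (adjusted p = 0.00281), where 17 lists were shifted in place of 10. For the 10 lists that camera shifted upward the adjusted p was 0.704 with an estimated correlation. Among these was the adipocyte list (camera adjusted p = 0.0212). Its mean was 7.78 in relapse against 5.92 in non-responder tumours of study 3, and 5.80 against 6.05 in study 2. In study 3 relapse replicate 3 it was 8.86, beside a B cell mean of 7.05. In all 1813 genes were higher and 2557 lower. The total of 4370 was 700 without study 2 relapse replicate 1, 1810 without replicate 3, and 1642, 2783 and 1163 without study 3 relapse replicates 1, 2 and 3, and 7514 without the 5 tumours low in melanocyte transcripts.

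Stabilization tumours, 3 in study 3, asked how arrested growth differs from regression and from growth. Against the 9 non-responders, macrophage and neutrophil transcripts were higher, with Mmp12, a macrophage elastase, at 3.55 ± 0.81 and S100a9 at 3.42 ± 0.84, and Cd274 at 1.42 ± 0.28. Pigment genes were lower, with Pmel at -2.84 ± 0.71 and Mlana at -2.54 ± 0.68. Of 16 macrophage genes 14 rose (15 adjusted over the list alone), of 12 neutrophil genes 9 rose (9), and of 17 melanocyte genes 11 fell (11). With an estimated correlation the adjusted p was 0.301, 0.301 and 0.388. The 2419 higher and 3269 lower genes rested on a single tumour: without stabilization replicate 1, whose melanocyte mean was 7.11, 1 gene passed, and without replicate 2, whose skeletal muscle mean was 11.20, 2057 did. Without the 5 tumours low in melanocyte transcripts, which leaves 1 stabilization tumour, 1 gene passed.

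Against the 10 responders, stabilization tumours had 14 higher and 6 lower genes. Higher were Inhba, an activin subunit (2.09 ± 0.37), Mmp10, a matrix protease (1.27 ± 0.22), Il11, a cytokine (1.19 ± 0.25), and Wnt5a, a Wnt ligand (1.16 ± 0.23). Lower were Tlcd4 (-2.13 ± 0.35) and Gpm6a, a membrane glycoprotein (-1.74 ± 0.40). The count of 20 was 1 without stabilization replicate 1, 61 without replicate 2, 1356 without replicate 3, and 0 with only the compared groups fitted, where limma's spread comes from these groups alone. Camera shifted 13 lists, 7 upward and 6 downward, and none passed with an estimated correlation (smallest adjusted p 0.275). The split was 1 upward and 15 downward without the 5 tumours low in melanocyte transcripts, which leaves 1 stabilization tumour and takes the spread from the other groups. There the macrophage list passed downward, where it had passed upward with all tumours.

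Growth delay tumours, 2 in study 2, were compared with the 14 IgG tumours. Gzmb had a value of -1.37 ± 0.82 and Cd274 of -0.38 ± 0.32, neither of which passed. The cytotoxic list mean was 6.00 ± 0.63 (SD, n = 2) and the interferon gamma list mean 9.79 ± 0.55, against 6.62 ± 0.53 and 9.84 ± 0.52 in IgG tumours (n = 14). By limma 0 genes passed, with 989 at an unadjusted p under 0.05, and 56 passed without growth delay replicate 1, where the remaining tumour is assumed to vary like the other groups. Camera shifted 1 list upward and 7 downward, among them macrophage (median -0.65), and each had an adjusted p of 0.952 with an estimated correlation.

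The 2 controls were compared to see how tumours given normal IgG differed from tumours given PBS. Cd274 (0.09 ± 0.19), Ifng (0.43 ± 0.39) and Gzmb (0.61 ± 0.48) did not pass (SE; 14 and 8 IgG against 3 and 4 PBS tumours). Eif2s3y, a gene of the Y chromosome, was the 1 gene that passed, with -1.03 ± 0.12 (adjusted p = 2.21e-08). Its mean was 3.28 in both groups of study 2, and 5.47 in PBS against 3.41 in IgG in study 3. By limma 1185 genes had an unadjusted p under 0.05, and leaving out study 3 PBS replicate 1 gave 51 genes. Camera shifted 13 lists upward, among them interferon gamma response (median 0.36) and MHC class I (median 0.26), with 0 members passing over all genes or adjusted over the list alone. The adjusted p with an estimated correlation was 0.292 for both, and none of the 13 passed. The interferon gamma list mean was 9.84 in IgG against 9.79 in PBS tumours of study 2, and 9.94 against 9.10 in study 3. The groups carry separate blocks of animal numbers in both studies, and those of study 3 lie far apart. The immediate early and heat shock list, a check on sample handling, also had higher means in IgG tumours. These means were 9.12 ± 0.28 (SD, n = 14) against 8.84 ± 0.12 (n = 3) in study 2, and 8.94 ± 0.27 (n = 8) against 8.64 ± 0.46 (n = 4) in study 3.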

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

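The tests of RNA quality and of sex-linked transcripts were chosen only after the result was seen, as was the use of a spread in weighing the scaling test and the part of Kdm5d and Uty in the sex test.

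More genes were lower than higher in responder against non-responder tumours (5885 and 3434), mostly among dim genes, where the 4 dimmest deciles had a median log2 fold change of -0.101. Each SE in this paragraph is over tumours and belongs to the mean of these genes per array, not to their median. Here it was 0.0159. The brightest decile also had more genes lower (655) than higher (323), with a median of -0.07 (-0.009 in study 2 and -0.127 in study 3), and what lowered it was not tested on its own. RNA quality, as far as the 3 prime to 5 prime difference measures it, is argued against as the whole cause: with this covariate, and without the 1 array at 5.2 where the others reach at most 0.935, 6183 genes were lower and 2865 genes followed the covariate. The tumours low in melanocyte transcripts are argued against as well, since the median was -0.105 (SE 0.0153) without these 5. Scaling of the arrays cannot be told apart from a change in the tumours: quantile normalization within study brought the median to -0.058 (SE 0.0116), which removes part of the shift. This value is past the bound of -0.05 that was written in advance against scaling, but by less than 1 SE. The outcome itself stays open as an untested biological explanation.

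A pair of tumours, 1 on each side of the responder comparison, had a B cell list mean above 9, study 2 non-responder replicate 14 (9.80) and study 3 responder replicate 3 (10.14). A candidate explanation is lymphoid tissue in the sampled piece. Of 9 measured members of the lymphoid chemokine and follicle list, not used to find the pair, 5 (Cxcl13, Ltb, Lta, Glycam1 and Clu) were higher in both than in each of the other 88 tumours. Glycam1, a ligand of high endothelial venules, was 11.88 and 12.49, against a highest other value of 10.19. Whether members such as Ltb and Lta only follow the lymphocytes that raise the B cell mean was not tested. Structures that form inside a tumour stay open and were not tested. A wrong outcome label alone would not give such a mean, since the highest B cell mean of the other 88 tumours, whatever their label, was 7.05.

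The 4 PBS tumours of study 3 stood apart in sex-linked transcripts, with Xist, the RNA of the inactive X chromosome, between 6.41 and 6.87 against at least 7.42 in the other 86. Eif2s3y was between 4.78 and 5.92 against at most 4.66. Host animals of the other sex cannot be told apart from another cause: all 4 lay outside the others in Xist and Eif2s3y, but Kdm5d (3.88 to 4.05) and Uty (3.87 to 4.13) lay within the others' ranges and near the floor. A mix-up of samples was not tested. The sex of the animals is not given in the sources used here, and the 4 tumours also share a block of animal numbers.

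Of 32 group measures tested for a tumour far from the rest, 6 passed Dixon's critical value, where chance gives about 1 in 20. All 32 came from the study 3 responder, non-responder, IgG and PBS groups, because only groups of 4 to 10 tumours were tested. Study 2 was therefore not tested, including its non-responder replicate 14 with a B cell mean of 9.80. In study 3 responders, replicate 3 was apart in the interferon gamma list (9.74 against 10.63 for the nearest; gap over range 0.594) and in the B cell list (10.14 against 5.84; 0.879), and replicate 4 in the cell cycle list (8.17 against 9.29; 0.566). Study 3 IgG replicate 3 was apart in the B cell list (5.72 against 5.29; 0.634). The 3 prime to 5 prime difference was apart in study 3 IgG replicate 7 (0.41 against 0.11; 0.621) and in study 3 PBS replicate 2 (5.2 against 0.59; 0.892).

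For 22 lists the responder against non-responder difference was not the same in both studies by camera, given here as the median log2 difference of study 3 minus study 2. None of the 22 passed with an estimated correlation (smallest adjusted p 0.246) or by fry, and 11 lists passed by camera without the 5 tumours low in melanocyte transcripts. The difference was 1.499 for skeletal muscle, 1.36 for adipocyte, 1.002 for MHC class II, 0.99 for plasma cell, 0.94 for T cell, 0.91 for B cell, 0.83 for cytotoxic effector and 0.71 for lymphoid chemokine genes. For checkpoint genes it was 0.62, for macrophage 0.53, for alternatively activated macrophage 0.51, for NK cell 0.49, for neutrophil 0.38, for dendritic cell 0.33 and for fibroblast genes 0.29. Inflammatory chemokine genes had 0.26, endothelial genes 0.23, MHC class I 0.21, mast cell and eosinophil 0.21, cell cycle -0.25, type I interferon -0.25 and melanocyte differentiation genes -0.70. Without the 5 tumours low in melanocyte transcripts, the melanocyte and cell cycle lists turned upward by camera and did not pass (adjusted p 0.310 and 0.132). The fibroblast and endothelium lists turned downward and did not pass (adjusted p 0.860 and 0.437).

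Other splits of the tumours within study, 100 for each comparison with the real one among them, tested whether chance can be excluded. At 1 split in 100, the smallest share these splits can give, chance is argued against for responder against non-responder. There only the real split reached 9319 genes, and the highest other gave 367. The same holds for responder against IgG (6436, highest other 2141) and for responder against non-responder in study 2 (478, highest other 24). It also holds for responder against IgG in study 2 (4973, highest other 22) and study 3 (3162, highest other 598). By the count of splits alone it holds for responder against non-responder in study 3 (6680, highest other 5134). The count alone also gives this for relapse against non-responder (4370, highest other 1342) and stabilization against non-responder (5688, highest other 5476). These counts were 2275 without the 5 tumours low in melanocyte transcripts, 700 without study 2 relapse replicate 1 and 1 without stabilization replicate 1, in that order. For stabilization another split came close to the real count, and for responders in study 3 another reached most of it. For non-responder against IgG in study 3, 2 splits, the real one included, reached 126, and the other gave 340. That count was 1 with only the compared groups fitted and 443 with default array weights. No split count here was adjusted over comparisons, and with 2 splits chance is left open for non-responder against IgG in study 3. Chance cannot be excluded for non-responder against IgG (8 splits reached 1; highest other 86), stabilization against responder (38 reached 20; 7815) or IgG against PBS (7 reached 1; 3). The test decides nothing for the counts of 0, which all 100 splits must reach, in non-responder against IgG in study 2 (highest other 2987), the difference between studies (8191) and relapse against responder (3395). Highest others far above the real count point to a structure of the samples, and what produces it was not tested.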

How the results depend on the processing

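Leaving out the 5 tumours low in melanocyte transcripts or study 2 non-responder replicate 14, the genebygene method of array weights, the skeletal muscle covariate and the 3 prime to 5 prime covariate with 1 array left out were chosen only after the result was seen. No paired analysis was possible because each tumour has its own animal number and replicate numbers only follow the order of the samples. The count for responder against non-responder stayed within 1.5 times under each alternative run, from 6996 to 10881. Its split was 3375 higher and 3621 lower with the filter on dim genes, which kept 13380 genes. Where no reason is given below, the cause was not tested. The default array weights stopped before their tolerance was reached and ran from 0.0261 to 133.7. Dim genes near the background limit what the arrays can show.

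Default array weights gave 3 genes for non-responder against IgG (443 in study 3), 7746 and 11008 in study 2 for responder against non-responder and IgG, 1903 for responder against IgG in study 3, 8 for the difference between studies, 7 and 10626 for relapse against responder and non-responder, 11512 and 13957 for stabilization against the same, 14 for growth delay and 4905 for IgG against PBS. In the same order, genebygene weights gave 3, 391, 8039, 10975, 1902, 9, 7, 10515, 5321, 9949, 10 and 2979, and 1 for non-responder against IgG in study 2.

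The mean of all probe sets gave 844 for responder against non-responder in study 2, 256 for non-responder against IgG in study 3 and 2 for IgG against PBS. With the filter on dim genes these counts were 154 and 36, for the first pair, and 0 for non-responder against IgG (fewer genes tested). Median centring, which moved the median of all genes by at most 0.0401, gave 2 for non-responder against IgG, 32 in study 3, 3 for the difference between studies and 1 for growth delay. Quantile normalization gave 296 and 2884 in study 2 for responder against non-responder and IgG, 55 for non-responder against IgG in study 3, 2 for the difference between studies, 2651 for relapse against non-responder and 9 for growth delay. The 3 prime to 5 prime covariate gave 12 for stabilization against responder. With the array of the largest 3 prime to 5 prime difference left out, this covariate gave 908 for responder against IgG and 31 for non-responder against IgG in study 3, 6 for the difference between studies and 2 for IgG against PBS. With study ignored, non-responder against IgG had 0 and relapse against non-responder 1621. With PBS and IgG pooled, non-responder against IgG had 0, and 47 in study 3, and responder against IgG in study 3 had 5386. Stabilization counted as response gave 7 for the difference between studies.

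With only the compared groups fitted, responder against non-responder had 169 in study 2 and 3141 in study 3, responder against IgG in study 3 had 1102, non-responder against IgG in study 3 had 1, stabilization against responder 0 and IgG against PBS 6. The skeletal muscle covariate gave 1057 for responder against non-responder in study 2 and 1884 for responder against IgG in study 3.

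Without the 5 tumours, responder against IgG had 3899 genes (3771 of them called with all tumours), and 1070 in study 3. Responder against non-responder had 4529 in study 2 and 2275 in study 3, non-responder against IgG 275 in study 3, relapse against non-responder 7514, stabilization against responder 0 and against non-responder 1 (1 stabilization tumour left), and IgG against PBS 2. Without study 2 non-responder replicate 14, non-responder against IgG had 2, responder against non-responder in study 2 had 2872, relapse against non-responder 5992 and the difference between studies 3.

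Leaving out 1 tumour of a small group at a time gave 700 to 3478 genes for relapse against non-responder, 0 to 56 for growth delay, 1 to 1356 for stabilization against responder and 1 to 7515 against non-responder. IgG against PBS ran from 1 to 51: 3 and 2 without study 2 PBS replicates 2 and 3, and 51, 2 and 2 without study 3 PBS replicates 1, 2 and 3. Relapse against responder stayed at 0 in all 6.

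With an estimated correlation 0 lists were shifted in each of the 16 comparisons. By fry the number was 0 for non-responder against IgG and within each study, for the difference between studies, relapse and stabilization against responder, growth delay and IgG against PBS, and 5 for responder against non-responder in study 2 and relapse against non-responder. For responder against non-responder fry shifted 17 lists upward and 2 downward, and for responder against IgG 15 upward and 1 downward. Without the 5 tumours camera shifted 12 lists for non-responder against IgG, 11 for the difference between studies, 17 for relapse and 11 for stabilization against non-responder, and without replicate 14 it shifted 10 for non-responder against IgG and 16 for relapse against non-responder.

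The list score difference for B cell genes passed without the 5 tumours (0.27, adjusted p = 0.000308) and without replicate 14 (0.51, adjusted p = 0.000252), as did that for melanocyte genes (-0.13, adjusted p = 0.00908; -0.38, adjusted p = 0.00576). These are permutation tests. At a threshold of 0.01, 87.2% of the study 2 calls (34 of 39) had the same sign in study 3, and 5 also passed there.

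Single genes kept direction and side of the threshold in 2617 cases and lost the threshold in 107, gained it in 31 and changed sign in 11. Hgf in responder against non-responder had 0.034 and 0.021 under the default and genebygene weights. Mlana in non-responder against IgG had 0.042 and 0.049 under these, and 0.03 both without the 5 tumours and without replicate 14. Foxp3 in responder against IgG had 0.002 with quantile normalization, 0.015 with PBS pooled and 0.005 without the 5 tumours. Mki67, responder against non-responder, passed under the default weights (0.371, adjusted p = 0.00311). Gzmb in relapse against non-responder ran from -0.051, without study 2 relapse replicate 1, to 0.674 as relapse tumours were left out. Il11 in stabilization against responder had -0.31 under the default weights, the 1 of these genes called in the first place.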

Other observations

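The test of Xist against the macrophage list was chosen only after the result was seen, and Xist was named after its values were seen.

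Xist differed between tumours of the same group and was higher in responders than in non-responders by 1.30 ± 0.28 (adjusted p = 0.000388; 17 and 10 against 14 and 9). A hypothesis is that Xist may follow the share of host cells in a tumour. It was tested in the 6 groups with at least 8 tumours against the macrophage and melanocyte list means, 12 relations in all, each with a permutation p. Xist rose with the macrophage list in 5 of the 6 groups. In study 2 responders (n = 17) Pearson's r was 0.910 (permutation p = 2e-05, adjusted 0.00024) and Spearman's rho 0.922 (permutation p = 2e-05), and r was 0.880 without the 2 farthest tumours. In study 3 responders (n = 10) r was 0.755 (permutation p = 0.00832, adjusted 0.0250) and rho 0.782 (permutation p = 0.00978), and r was 0.580 without the 2 farthest.

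In study 2 IgG tumours (n = 14) r was 0.699 (permutation p = 0.0167, adjusted 0.0333) and rho 0.446 (permutation p = 0.111), and in study 2 non-responders (n = 14) 0.824 (permutation p = 0.00774, adjusted 0.0250) and 0.596 (permutation p = 0.0279). In study 3 IgG tumours (n = 8) r was 0.828 (permutation p = 0.0152, adjusted 0.0333) and rho 0.690 (permutation p = 0.0694). In these groups the relation rests on the 2 farthest tumours, since r without them was 0.420, 0.328 and 0.236. Study 3 non-responders (n = 9) gave r 0.358 and rho 0.383, which did not pass (permutation p = 0.343, adjusted 0.374; permutation p = 0.312), and r -0.282 without the 2 farthest.

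Against the melanocyte list, Xist fell in study 2 responders (r -0.675, permutation p = 0.00234, adjusted 0.0140; rho -0.743, permutation p = 0.00132; r -0.625 without the 2 farthest). In study 2 non-responders r was -0.800 (permutation p = 0.0239, adjusted 0.0396; rho -0.385, permutation p = 0.175) and in study 3 responders -0.816 (permutation p = 0.0264, adjusted 0.0396; rho -0.479, permutation p = 0.166). Both rest on the 2 farthest tumours, with r -0.373 and 0.137 without them. The other 3 groups did not pass and had r above 0, the direction opposite to that of the hypothesis: 0.155 in study 2 IgG tumours, 0.562 in study 3 IgG tumours and 0.561 in study 3 non-responders (permutation test, adjusted p 0.603, 0.206 and 0.160).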
